A study of Mus musculus with 6 samples.

How the data were processed

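RNA was measured in 6 samples of mouse hippocampal primary neurospheres, 3 grown with 10 µM norepinephrine and 3 with 15 mM KCl, all collected on day 14. Per the labels' protocols, total RNA was extracted with TRIzol, treated to remove genomic DNA and converted to labelled cDNA with the NuGEN Applause WT-Amp ST kit. The labels also state that 2 of the replicates were shared with RNA sequencing data, which were not analysed here. Treatment and replicate number of each array were taken from the sample titles and treatment labels.

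The deposited values are log2 expression values per probe set, and the submitters' processing notes name Partek and RMA, a method that combines background correction, quantile normalization and summarization of probes. Their versions and settings, such as the probes used, are not given in the sources used here. The deposited log2 values differed in distribution between arrays, with interquartile ranges from 1.48 to 2.39 over the named probe sets, although quantile normalization as usually run makes distributions alike over all probes before summarization. How much of the array difference arose before or after that step is not known. No scanner files were used here, so signal over background could not be assessed, and no probe set was left out as undetected. On KCl replicate 1 bright genes read low and dim genes high, which raises norepinephrine minus KCl for bright genes and lowers it for dim ones, so each count was also computed without KCl replicate 1.

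The table held 34760 probe sets. The platform table listed 1 gene symbol for 21640 of them, several symbols for 1321 and none for 11799, and these last are unnamed here. Of the named probe sets, 21553 were matched by Entrez identifier to the RefSeq gene table of the GRCm38.p6 assembly, which changed 0 symbols. No coordinates are printed, since the genome build of the platform is not given in the sources used here. The named probe sets covered 19937 genes, of which 954 had more than 1 probe set. Where a gene needed a single value, the probe set with the highest mean over the 6 arrays was taken. Several probe sets of a gene did not always agree, and this is given for Plp2, Lsm7, Hmcn1, Chd7 and Rpl19.

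The comparison of the treatments used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options) on the deposited log2 values of the 21640 named probe sets, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. Differences are norepinephrine minus KCl, with moderated standard errors. Fitted with no covariate, the model left the replicate number out, because the labels do not say that equal numbers mark a shared animal or culture.

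For groups of genes, 36 lists with 986 entries were written before the data were examined, as were the design, the tests and the alternatives. Of the entries, 890 were measured under a single symbol, and the others were not analysed here. The lists covered stem cell and quiescence genes, neurons, astrocytes and oligodendrocytes, cell division, activity, cAMP, calcium and adrenergic genes, signalling pathways, metabolism, stress and interferon genes, regional identity, and markers of microglia, endothelium, pericytes and ependyma. A list was called when camera in limma, with a preset correlation of 0.01 between genes, gave an adjusted p under 0.05 over the lists. Beside it stood camera with a correlation estimated per list, and fry, which asks whether the genes of a list move one way on balance and compares them with no other genes. Members of a list were also adjusted over the list alone. The median of each list was also set against 10000 random lists of the same size matched on mean brightness and gene length. These drew genes singly and held the arrays fixed. Their percentiles therefore carry neither genes that move together nor the spread between samples.

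The genes named singly were set by a rule. From genes whose mean over the 6 arrays lay above the 30th percentile, it took the 12 largest differences in each direction past the adjusted threshold. As none passed, it was filled up with genes at an unadjusted p under 0.05 whose groups did not overlap, 470 in all. Predicted genes, clones, olfactory and vomeronasal receptors and small RNA genes were left out of this part, which removed 16. All measured members of the adrenergic list and up to 4 members of smallest p in a described list were added. Probe sets of named genes other than the representing one were looked at after their values were seen.

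Alternatives tried were a further quantile normalization, centring of each array, filters on dim probe sets at the 30th percentile and the median, trend and robust variance moderation, array weights, the replicate number as a block, other choices of probe sets and thresholds, and leaving out each array. Array weights by the gene-by-gene method, the estimated correlation without KCl replicate 1 and the counts at an unadjusted p were added after the data were seen. The limma step was tested on simulated data for 21640 probe sets with 200 changed. With the spread of all 6 arrays it recovered 9% of 2-fold and 80% of 4-fold changes with 2 false calls, and with the spread without KCl replicate 1 it recovered 73% and 96% with 6. Both simulations kept 6 arrays. The latter shares are therefore not those of the comparison without KCl replicate 1, which had fewer arrays. In both, genes were drawn independently with the same spread on every array, so no array stood apart as KCl replicate 1 did. In simulated lists of 25 genes each of the 3 list tests called 5 of 5 shifted lists. Of 20 unshifted lists, both camera tests called 0 and fry 1. The simulated genes varied independently of one another. These counts therefore do not show how the tests fare on lists whose genes move together between samples. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the table, and matplotlib 3.10.9 drew the plots.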

Results

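Gene expression was measured in primary neurospheres, the floating colonies that neural precursor cells form in culture, grown from the hippocampus of adult male C57BL/6J mice aged 8 to 12 weeks. The cells were kept in medium with the growth factors EGF and bFGF. To this, 10 µM norepinephrine, a monoamine transmitter, or 15 mM KCl, which depolarises neurons, was added, and the spheres, called big neurospheres in the labels, were harvested on day 14. Each treatment had 3 samples, each run on 1 whole-transcript array. No untreated group was analysed here, so every difference is norepinephrine minus KCl and does not show which treatment moved a gene away from its untreated level. The labels call the samples biological replicates. Whether each came from a separate animal or culture is not given in the sources used here, so the p-values measure the spread between these samples. The array of KCl replicate 1 stood apart from the other 5, with a standard deviation of 1.38 log2 units over the named probe sets against 1.62 to 1.78. Values without it are therefore given beside the gene groups. All values are log2 expression values, and the number of arrays limits their precision.

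The first comparison asked which genes were up or down between the treatments. Among the genes chosen by a fixed rule, the largest values toward norepinephrine were those of Pcbd1, an enzyme that regenerates the cofactor tetrahydrobiopterin, at 2.10 ± 0.44 (log2 difference ± SE, n = 3 per group), and of the membrane protein Plp2 at 1.95 ± 0.42. The 3 probe sets of Plp2 ranged from 0.18 to 1.95, with a median of 1.16. Gfap, the intermediate filament of astrocytes and of hippocampal neural stem cells, followed at 1.89 ± 0.30, a 3.71-fold difference. Its probe set, 10391798, read 8.31 ± 0.43 (SD) with norepinephrine and 6.42 ± 0.48 with KCl. Gng3, a G protein gamma subunit, differed by 1.84 ± 0.23, and its readings were 9.72 ± 0.36 and 7.88 ± 0.20. On the other side stood Hmcn1, which encodes hemicentin 1, a large extracellular matrix protein, at -1.59 ± 0.25. Its representing probe set, 10358666, read 7.09 ± 0.14 with norepinephrine and 8.68 ± 0.45 with KCl.

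The other genes of this rule that were higher with norepinephrine were Minar2 at 1.73 ± 0.25, the arsenic methyltransferase As3mt at 1.68 ± 0.32 and Gpnmb, a transmembrane glycoprotein of lysosomes, at 1.63 ± 0.47. Norepinephrine replicate 2 read highest for Gpnmb, at 9.80, and the SD of that group was 1.12. The Gpnmb difference was 0.99 without that array. Prrg4 differed by 1.60 ± 0.45, and the RNA-binding ring subunit Lsm7 by 1.55 ± 0.48, with 1.09 on its other probe set. Mpc1, a subunit of the mitochondrial pyruvate carrier, differed 2.82-fold, with an SE of 0.47 log2 units. Thy1, a surface glycoprotein of neurons and fibroblasts, differed by 1.47 ± 0.35 and Mmd2 by 1.40 ± 0.27. With KCl replicate 1 left out, the differences of Pcbd1, Plp2, Prrg4, Lsm7 and Mpc1 were 1.63, 1.46, 1.01, 0.93 and 0.94.

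Among the genes higher with KCl by this rule, Cacna2d3, an auxiliary subunit of voltage-gated calcium channels, differed by -1.34 ± 0.25, the integrin subunit Itga4 by -1.32 ± 0.24 and the receptor Cd93 by -1.15 ± 0.29. The cadherin Cdh19 differed by -0.96 ± 0.31 and the gap junction protein Gjc1 by -0.93 ± 0.27. Epb41l4a stood at -1.59 ± 0.32, the chromatin remodeller Chd7 at -1.07 ± 0.32 and the lipid kinase Pip5k1b at -1.03 ± 0.24. Trp53i11 differed by -1.02 ± 0.35, the tyrosine kinase Frk by -0.98 ± 0.17 and the imprinted gene Peg10 by -0.93 ± 0.31. Of the 77 probe sets of Hmcn1, 74 were higher with KCl, with a median of -0.44. Of the 30 probe sets of Chd7, 26 were higher with KCl, with a median of -0.48. The Chd7 difference was -0.67 without KCl replicate 1, and that of Trp53i11 was -0.62 without KCl replicate 3.

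None of these 24 genes, which the rule picked for groups that did not overlap, passed the test. By limma with Benjamini-Hochberg adjustment, 0 of 21640 probe sets had an adjusted p under 0.05, and the lowest adjusted p was 0.662. At an unadjusted p under 0.05 there were 743 probe sets, 475 higher with norepinephrine and 268 higher with KCl, where chance alone gives about 1082. This balance was 515 and 486 without KCl replicate 1, and 548 and 448 after a further quantile normalization. The groups did not overlap in 1975 probe sets, or 9.13%, and chance gives 10%. Without KCl replicate 1, 4 probe sets passed: Gfap at 2.17 ± 0.24 (adjusted p = 0.045) and 3 further Hmcn1 probe sets at -2.09 ± 0.17, -1.42 ± 0.16 and -2.21 ± 0.18 (adjusted p = 0.00695, 0.045 and 0.00695). In data simulated with the spread of all 6 arrays, the same test recovered 9% of genes changed 2-fold and 80% of genes changed 4-fold. The simulated genes varied independently and no simulated array stood apart, so these shares may not hold for the real arrays.

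**Figure D1:**
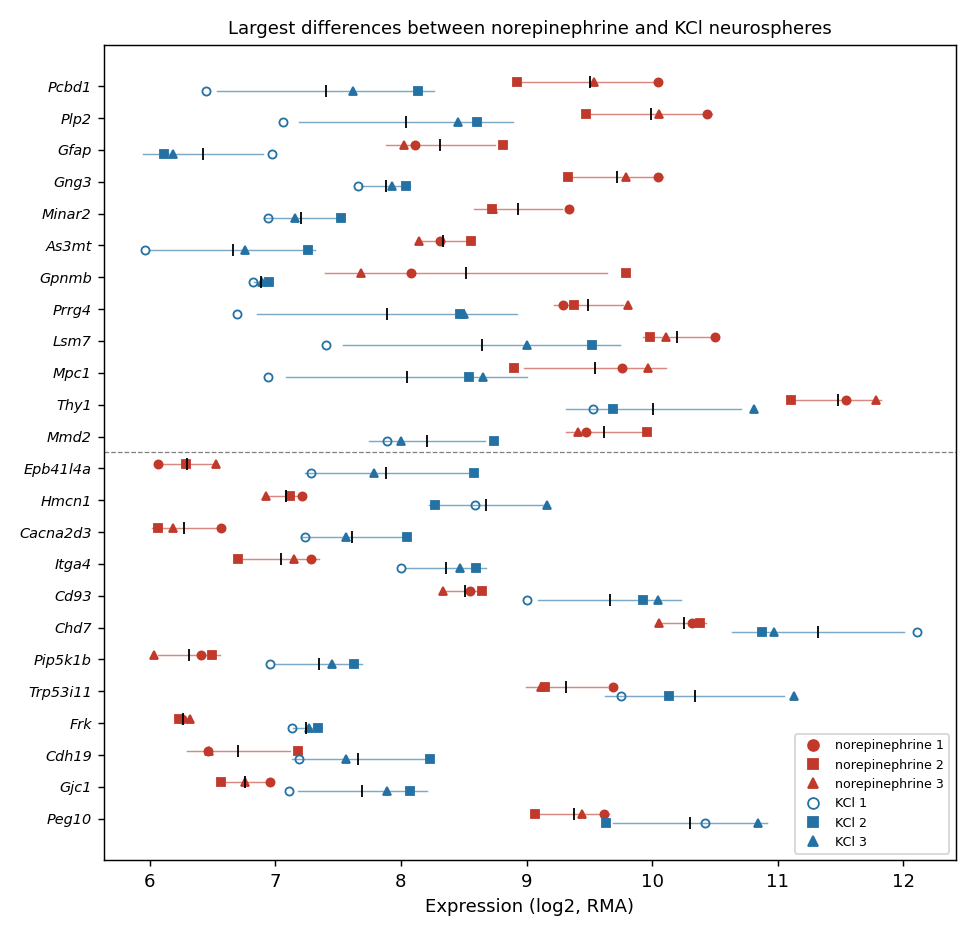
Expression of the 24 genes named by the fixed rule, in log2 RMA units on the horizontal axis, with 1 symbol per array, a black tick at each group mean and a line of 1 SD to each side (n = 3 per group). Red symbols are norepinephrine and blue symbols KCl, the open circle is KCl replicate 1, and the broken line parts genes higher with norepinephrine from genes higher with KCl. None of them passed the adjusted threshold on all 6 arrays.

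Gene lists fixed in advance were tested next, to describe groups of genes rather than single ones. Markers of astrocytes, the support glia of the brain, were higher with norepinephrine in 21 of 25 measured members, with a median difference of 0.38. Gfap was joined by the lipid carrier Apoe, at 11.07 ± 0.22 against 9.88 ± 0.23 (SD), by the secreted chaperone clusterin (Clu), at 8.83 ± 0.12 against 7.79 ± 0.14, and by the water channel Aqp4, at 7.96 ± 0.17 against 6.78 ± 0.32. These 4 genes passed when adjusted over the list alone, with adjusted p = 0.00297 for Gfap, Apoe and Clu and 0.00344 for Aqp4, and 0 passed over all genes. The list mean was 8.86 to 8.88 on the norepinephrine arrays, 8.46 and 8.51 on KCl replicates 2 and 3 and 8.14 on KCl replicate 1. The list was called by camera with a preset correlation (adjusted p = 7.7e-13). The call was lost with an estimated correlation (adjusted p = 0.0985 with an estimated correlation) and with fry (adjusted p = 0.183). Camera with the preset correlation also called this list in some splits of the arrays that mixed the treatments, with 5.9e-06 as the lowest adjusted p there. The median was 0.29 when KCl replicate 1 was left out.

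Lists of stem cell and reactive glia genes shared members with the astrocyte list, among them Gfap, Apoe and Clu. Of 25 genes associated with stem cell quiescence, 19 were higher with norepinephrine, and the median was 0.19. Ndrg2, a gene expressed in astrocytes, differed by 1.40 ± 0.22 and passed with Apoe and Clu, at adjusted p = 0.00297 for each, when adjusted over the list alone. Hopx, a marker of quiescent hippocampal stem cells, differed by 0.87 ± 0.26 and did not pass (adjusted p = 0.0503 over the list alone). Of 25 neural stem and radial glia markers, 17 were higher with norepinephrine, with a median of 0.11. In that list Gfap was the 1 gene to pass when adjusted over the list alone, while Id3, an inhibitor of differentiation, differed by 0.76 ± 0.24 and Prom1 by 0.60 ± 0.21. Of 21 reactive astrocyte genes, 13 were higher with norepinephrine, and the median was 0.17. Gfap, the interferon-induced chemokine Cxcl10 at 1.31 ± 0.37, the metalloproteinase inhibitor Timp1 at 0.90 ± 0.26 and the serpin Serpina3n at 0.63 ± 0.19 passed over that list alone.

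Camera called the quiescence, neural stem and reactive astrocyte lists, with adjusted p = 1.3e-07, 0.000304 and 0.000648. All 3 calls were lost with an estimated correlation (adjusted p = 0.29, 0.204 and 0.29 with an estimated correlation). Their medians were 0.21, 0.13 and 0.18 without KCl replicate 1. When KCl replicate 2 was left out, the neural stem median was 0.018 and the quiescence median 0.38, and the latter was 0.30 without KCl replicate 3. No member of these lists passed over all genes. Of the 26 genes of interferon response and antigen presentation, 20 were higher with norepinephrine. Their median was 0.16, or 0.15 and 0.087 without KCl replicates 1 and 2, and 2 members had an unadjusted p under 0.05, Cxcl10 and the interferon-induced Ifit3 at 1.07 ± 0.33 (0.69 without norepinephrine replicate 3). This list was called too (adjusted p = 0.000526), and not with an estimated correlation (adjusted p = 0.29 with an estimated correlation).

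Markers of neurons and oligodendrocytes were not called on 6 arrays. In the neuroblast list of 30 genes the cytoskeletal regulator Dpysl3 stood at 0.60 ± 0.20, the growth cone protein Gap43 at 0.58 ± 0.19 and neuronal tubulin Tubb3 at 0.47 ± 0.18, whereas the surface antigen Cd24a stood at -0.45 ± 0.19. The list median was -0.046, its mean 0.042, and camera gave an adjusted p of 0.302. Among 25 mature neuron markers the synaptic protein Snap25 stood at 1.03 ± 0.27 and the calcium buffer Pvalb at 0.58 ± 0.23, with a list median of -0.0047, a mean of 0.03 and an adjusted p of 0.557. The 18 markers of oligodendrocyte precursors had a median of 0.06 (adjusted p = 0.0711), with Gpr17 at 0.70 ± 0.25 and the PDGF receptor Pdgfra at 0.66 ± 0.24. The precursor list was called without norepinephrine replicate 1, at 0.044 (adjusted p = 0.03), and without KCl replicate 3, at 0.125 (adjusted p = 0.0379). The medians of the precursor and mature neuron lists were 0.07 and 0.12 without KCl replicate 1. When KCl replicate 2 was left out, all 4 of these lists had medians below 0, at -0.19 for neuroblasts, -0.117 for mature neurons, -0.007 for precursors and -0.269 for myelinating markers, and none was called. The 21 myelinating oligodendrocyte markers had a median of -0.05, a mean of 0.07 and an adjusted p of 0.302. Among them were Trf at 1.21 ± 0.39 (0.79 without KCl replicate 1), Tspan2 at 0.85 ± 0.23 and Aspa at -0.56 ± 0.20. On the 5 arrays other than KCl replicate 1, the neuroblast list had a median of 0.12 and was called higher with norepinephrine (adjusted p = 0.0342), as was the myelinating list at 0.13 (adjusted p = 0.0285). Neither was called there with an estimated correlation (adjusted p = 0.868 and 0.698 with an estimated correlation).

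On 6 arrays the largest list median was that of oxidative phosphorylation, the mitochondrial respiratory chain, at 0.52, with 33 of 33 members higher with norepinephrine. The complex I subunits Ndufb10 and Ndufb8 stood at 1.03 ± 0.35 and 0.80 ± 0.29, and the complex III subunit Uqcrq at 0.78 ± 0.24. Of these members, 7 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. The list mean was 9.35 on KCl replicate 1 and 10.1 to 10.6 on the other 5 arrays. Without that array the median was 0.27, and 0.58, 0.62 and 0.49 for Uqcrq, Ndufb10 and Ndufb8. Camera called the list (adjusted p = 3.6e-19), but not with an estimated correlation (adjusted p = 0.29 with an estimated correlation). Of 24 ribosomal protein genes, 22 were higher with norepinephrine, with a median of 0.39 that was 0.11 without KCl replicate 1. Random lists of like brightness and gene length had medians of 0.37 and 0.16 on the same arrays, so this list was no higher than matched genes. Rpl19 stood at 0.54 ± 0.25, and at 0.28 without that array, while its 6 probe sets ranged from 0.0039 to 0.73. That list was called (adjusted p = 1.3e-07), and not with an estimated correlation (adjusted p = 0.332 with an estimated correlation).

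Genes of cell division were read in 3 lists. Of 34 genes of mitosis and G2/M, 29 were higher with norepinephrine, and the median was 0.29, or 0.13 and 0.44 without KCl replicates 1 and 2. Nusap1, a spindle protein, stood at 0.47 ± 0.22. The list was called (adjusted p = 1.26e-07), and not with an estimated correlation (adjusted p = 0.332 with an estimated correlation). Of 33 genes of DNA replication and S phase, 18 were higher with norepinephrine, the median was 0.028 (-0.08 without KCl replicate 1) and the adjusted p 0.464. That list was called without KCl replicate 2, at 0.15 (adjusted p = 0.00358). Mcm2, a subunit of the replicative helicase, stood at -0.28 ± 0.18. Of 16 replication-dependent histone genes, 11 were higher with norepinephrine, with a median of 0.13 that was 0.25 without KCl replicate 1. The call (adjusted p = 0.00798) ended without norepinephrine replicate 3, KCl replicate 2 or KCl replicate 3, where the medians were 0.068, 0.127 and 0.062 (adjusted p = 0.0585, 0.0601 and 0.145). The list was also not called with an estimated correlation (adjusted p = 0.29 with an estimated correlation).

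For 7 further lists camera's call was present on all 6 arrays and absent without KCl replicate 1. Of 26 genes of hypoxia and glycolysis, 21 were higher with norepinephrine, among them carbonic anhydrase Car9 at 1.09 ± 0.30, phosphofructokinase Pfkp at 0.82 ± 0.27 and the glucose transporter Slc2a1 at 0.71 ± 0.28, whereas the hypoxia-induced Ankrd37 stood at -0.50 ± 0.20. Pfkp and Slc2a1 stood at 0.54 and 0.45 without KCl replicate 1. The list median of 0.31 (adjusted p = 6.7e-05) was 0.0013 without KCl replicate 1 (adjusted p = 0.567). The lysosome and autophagy list, which holds Gpnmb, had a median of 0.25 and the heat shock list one of 0.21 (adjusted p = 5.8e-07 and 0.00074). Their medians were 0.03 and 0.04 without that array (adjusted p = 0.252 for both). The cholesterol synthesis list at 0.26, the integrated stress and unfolded protein response list at 0.15 and the circadian clock list at 0.14 were called with adjusted p = 0.000946, 0.00616 and 0.00723. Their medians without that array were 0.02, 0.03 and 0.07. Of 24 markers of microglia and macrophages, the immune cells of the brain, 22 were higher with KCl, with a median of -0.24 (adjusted p = 0.00115). Its members Ly86 and Mpeg1 stood at -0.47 ± 0.20 and -0.43 ± 0.19. Without KCl replicate 1, on which this list's mean was 6.79 against 6.06 to 6.33 elsewhere, the median was -0.01. Without KCl replicate 2 the medians of the hypoxia, lysosome, heat shock, cholesterol and microglia lists were 0.497, 0.501, 0.375, 0.478 and -0.391. The cholesterol median was 0.17 without norepinephrine replicate 1, and the circadian median was 0.236 without norepinephrine replicate 3 and 0.237 without KCl replicate 3. The heat shock, stress and circadian calls also ended after a further quantile normalization (adjusted p = 0.107, 0.207 and 0.163), at medians of 0.058, 0.099 and 0.144. With an estimated correlation no call of these 7 lists held. For the hypoxia, lysosome, heat shock and cholesterol lists the adjusted p was 0.332, 0.353, 0.332 and 0.519 with an estimated correlation. For the stress, circadian and microglia lists it was 0.332, 0.332 and 0.701.

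In all, camera called 16 of the 36 lists on 6 arrays, 15 higher with norepinephrine and 1 higher with KCl. Neither camera with an estimated correlation nor fry called any, and the lowest adjusted p was 0.0985 and 0.183, in both cases for astrocyte markers. Without KCl replicate 1 camera called 12 lists, of which 9 were among the 16, and 0 were called with an estimated correlation. With probe sets under the median left out, 7 of the 16 were still called. The calls lost there were those of the neural stem, interferon, histone, hypoxia, heat shock, cholesterol, stress and circadian lists (adjusted p = 0.0512 to 0.343), and the microglia list had too few genes left. The medians of these lists were 0.114, 0.166, 0.199, 0.322, 0.203, 0.277, 0.172 and 0.14 in that order, while the median over all probe sets went from -0.07 to 0.06 under this filter.

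**Figure D2:**
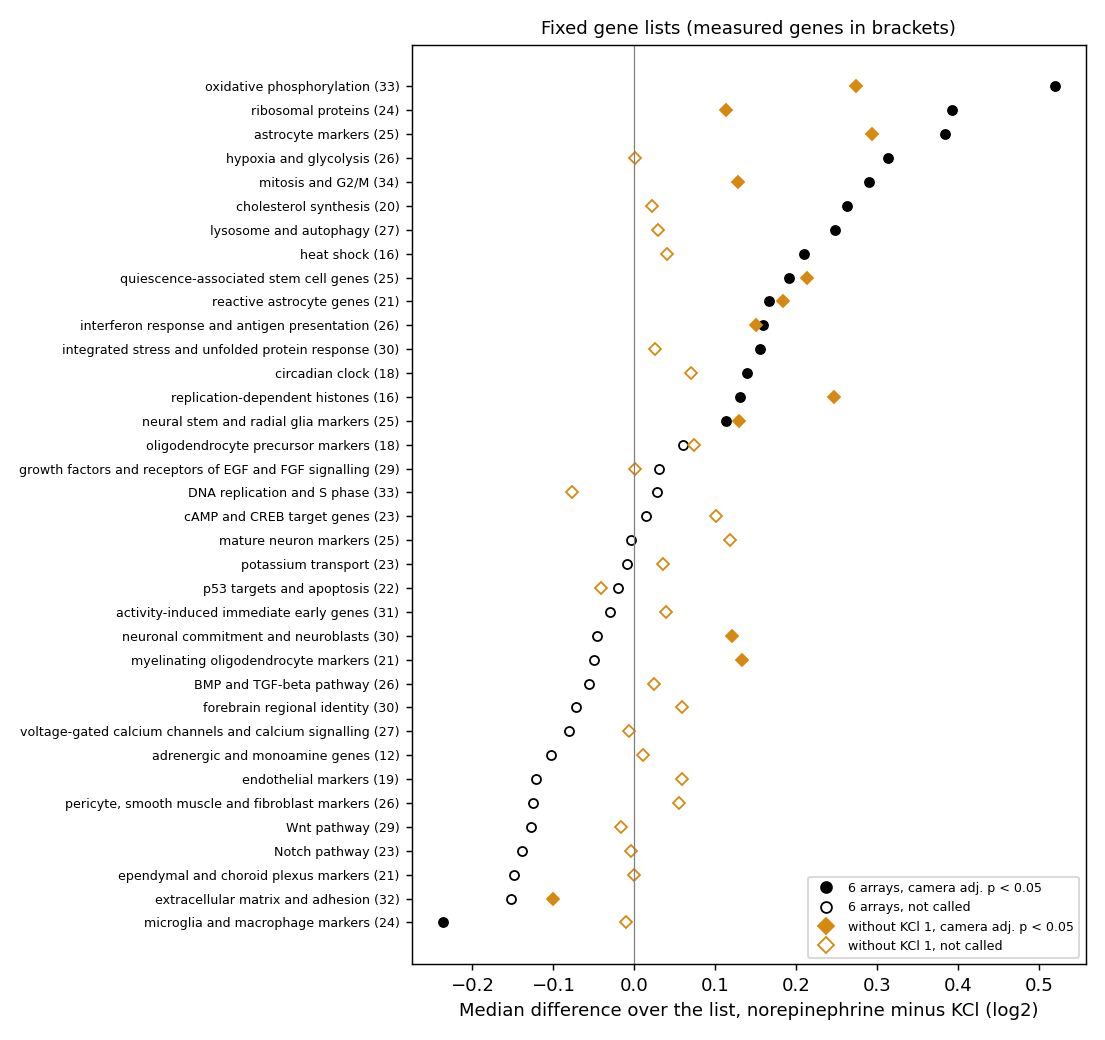
Median log2 difference, norepinephrine minus KCl, of each of the 36 fixed gene lists, with the number of measured genes in brackets. Black circles are the values on 6 arrays and orange diamonds those without KCl replicate 1, and filled symbols are lists called by camera with a preset correlation of 0.01 at an adjusted p under 0.05. Oxidative phosphorylation had a median of 0.52 on 6 arrays and 0.27 without KCl replicate 1, and no list was called with an estimated correlation.

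Because one treatment acts through adrenergic receptors, the 12 measured genes of the adrenergic and monoamine list were read in both groups. The receptor genes Adra1b and Adra2c read 6.29 ± 0.09 and 5.83 ± 0.19 (SD) with norepinephrine and 6.43 ± 0.47 and 6.07 ± 0.31 with KCl, differences of -0.14 ± 0.25 and -0.24 ± 0.22 (SE). The filter on dim probe sets at the 30th percentile kept 7 of the 12 genes and left out both of these receptor genes, Slc6a4, Maob and Dbh. The readings of the genes left out therefore do not show that they were expressed. The monoamine oxidase Maoa read 8.81 ± 0.55 and 8.43 ± 1.05, a difference of 0.38 ± 0.49, and Maob differed by -0.03 ± 0.25. The receptor kinases Grk3 and Grk5 differed by -0.11 ± 0.22 and 0.13 ± 0.19. The norepinephrine transporter Slc6a2 differed by -0.33 ± 0.22, the dopamine transporter Slc6a3 by -0.28 ± 0.23, the serotonin transporter Slc6a4 by -0.20 ± 0.22 and the monoamine transporter Slc29a4 by 0.15 ± 0.25. Th and Dbh, the synthetic enzymes of catecholamines, differed by -0.10 ± 0.24 and -0.08 ± 0.25. None passed over all genes or when adjusted over the list alone, where the lowest adjusted p was 0.826. The list as a whole had a median of -0.10 and was not called (adjusted p = 0.557), and the median was 0.011 without KCl replicate 1. Leaving out 1 array at a time moved Slc6a2 between -0.51 and -0.14, Slc6a3 between -0.49 and -0.11 and Adra2c between -0.39 and -0.08. Grk5 lay between 0.067 and 0.245. Other genes of this system were not analysed here.

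Genes downstream of membrane depolarisation and of cAMP were likewise not called as groups on 6 arrays. Of 31 activity-induced immediate early genes, 14 were higher with norepinephrine, with a median of -0.03 (adjusted p = 0.839). Ier3 stood at 0.77 ± 0.35, or 0.33 without KCl replicate 1, and Atf3 at -0.39 ± 0.18. The 23 cAMP and CREB target genes had a median of 0.015 (adjusted p = 0.0746), with the thyroid hormone deiodinase Dio2 at 0.62 ± 0.24 and the small GTPase Gem at 0.45 ± 0.18. They were called without norepinephrine replicate 2, at 0.108 (adjusted p = 0.0124), and without KCl replicate 3, at 0.076 (adjusted p = 0.0178), but stood at -0.087 without norepinephrine replicate 1 and at -0.11 without KCl replicate 2. The 27 genes of calcium channels and calcium signalling had a median of -0.08 (adjusted p = 0.681). Cacna2d3 passed there when adjusted over the list alone (adjusted p = 0.0156), while the calcineurin regulators Rcan2 and Rcan1 stood at 0.95 ± 0.24 and 0.69 ± 0.28. The Rcan1 difference was 0.38 without KCl replicate 1. The 23 potassium transport genes had a median of -0.0087 and a mean of 0.11 (adjusted p = 0.0689), with the channel Kcnn2 at 0.74 ± 0.21 and the sodium-potassium pump subunit Atp1b2 at 0.69 ± 0.23. They were called higher with norepinephrine without norepinephrine replicate 1, at a median of -0.003 (adjusted p = 0.0421), and without KCl replicate 3, at 0.099 (adjusted p = 0.00925). The medians of the immediate early, cAMP, calcium and potassium lists were 0.039, 0.10, -0.0071 and 0.035 without KCl replicate 1.

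Of the signalling lists, that of the BMP and TGF-beta pathway had a median of -0.056, while camera's sign was toward norepinephrine (adjusted p = 0.91). It held Id3 and, at -0.58 ± 0.21, the activin antagonist Fst. The Notch list had a median of -0.14 (adjusted p = 0.557), with its effector Hey2 at 0.55 ± 0.19, the Wnt list one of -0.13 (adjusted p = 0.199) and the EGF and FGF list one of 0.03 (adjusted p = 0.143). The list of p53 targets and apoptosis had a median of -0.021 and a mean of 0.08 (adjusted p = 0.143), and that of forebrain regional identity a median of -0.07 (adjusted p = 0.525). The p53 list was called without KCl replicate 2, at 0.28 (adjusted p = 0.00306), and the EGF and FGF list without KCl replicate 3, at 0.151 (adjusted p = 0.00593). The Notch list was called with probe sets under the median left out, at -0.17 (adjusted p = 0.0153). On the arrays other than KCl replicate 1 the Notch and Wnt medians were -0.004 and -0.017, and the Wnt median was -0.253 without KCl replicate 2. Those of the BMP, EGF and FGF, p53 and regional lists were 0.024, 0.0008, -0.041 and 0.059 without KCl replicate 1. Extracellular matrix and adhesion genes were higher with KCl in 23 of 32 members, with a median of -0.15 (adjusted p = 0.255). This list was called when KCl replicate 1 was left out, at a median of -0.10 (adjusted p = 0.00816), though not with an estimated correlation (adjusted p = 0.448 with an estimated correlation). It was also called after a further quantile normalization of the 6 arrays, at a median of -0.20 (adjusted p = 0.00188), and with probe sets under the 30th percentile or the median left out (adjusted p = 0.036 and 0.0148). Among other cell types, endothelial markers had a median of -0.12 (adjusted p = 0.084) and markers of pericytes, smooth muscle and fibroblasts one of -0.13 (adjusted p = 0.684), the latter list including Thy1. Endothelial markers were called without KCl replicate 2, at -0.314 (adjusted p = 0.0263), and stood at 0.059 without KCl replicate 1 (adjusted p = 0.669). Ependymal and choroid plexus markers had a median of -0.15 (adjusted p = 0.525). The pericyte and ependymal medians were 0.055 and -0.0011 without KCl replicate 1. The adipokine Rarres2, at 1.03 ± 0.20, was the 1 gene of that list to pass when adjusted over the list alone (adjusted p = 0.0149).

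The last comparison asked whether treatment was the main difference between the arrays. The grouping by treatment held 20.1% of the summed variance. Of the 10 splits of the arrays into 3 and 3, 4 gave at least this share, with the real one included. The highest other gave 35.1%, so the share is not above what groups mixing the treatments gave. The first principal component, with 70.0% of the variance, set KCl replicate 1 at a score of 85.7 against -40.1 to 4.95 for the others. The second component held 13.7%. Bright genes read low on KCl replicate 1 and dim genes high. Its brightest 5% of probe sets lay at a median of -0.70 from the mean of the other arrays and its dimmest 25% at 0.55. Its correlation with the others was 0.881 to 0.929, whereas pairs among those 5 reached 0.970 to 0.989. Norepinephrine replicate 2 correlated most with KCl replicate 2 (r = 0.987). No arrays held identical values. The median difference over all probe sets was -0.07, and 0.0083 without KCl replicate 1.

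**Figure D3:**
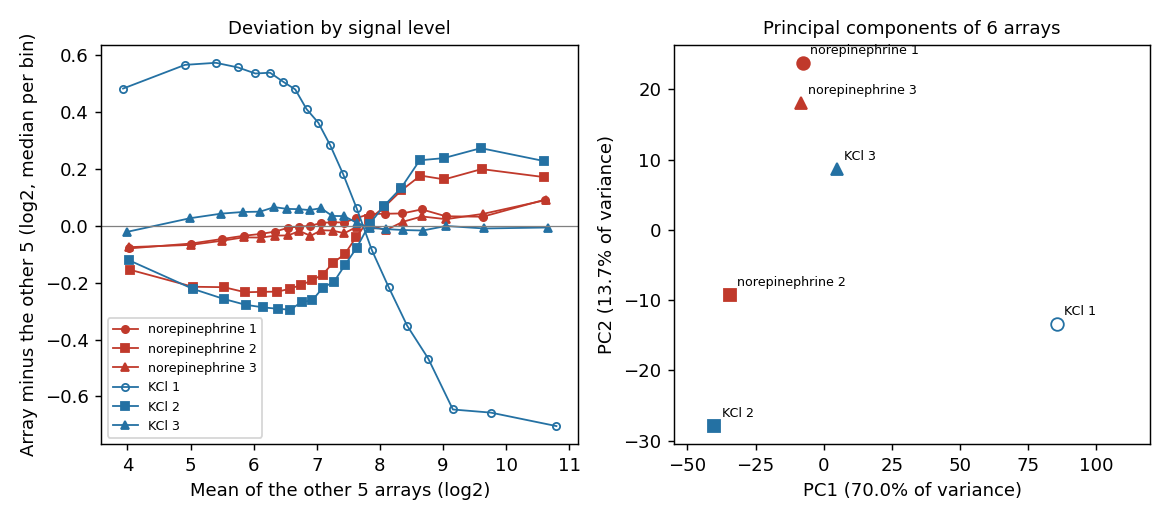
Left, the median deviation of each array from the mean of the other 5 (log2), in bins of that mean (log2). Right, the scores of the 6 arrays on the first 2 principal components, which held 70.0% and 13.7% of the variance. Red is norepinephrine, blue is KCl, and KCl replicate 1, the open circle, lies apart in both panels.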

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

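Counts of genes were set by the weighting of arrays more than by other choices. The 0 probe sets past the adjusted threshold stayed 0 under both scalings, both filters on dim probe sets, trend and robust moderation, the other choices of probe sets, a threshold of 0.10 and the replicate block, and 486 met an unadjusted p under 0.05 with a 1.5-fold difference. Array weights gave 5670 and, by the gene-by-gene method added after seeing the data, 1454. The first set of weights did not converge and put a weight of 672.7 on KCl replicate 3, so those calls rest on that array and are not used. The gene-by-gene weights also leaned on KCl replicate 3, at 6.763 against 0.158 and 0.288 for KCl replicates 1 and 2. By the first set of weights 3 adrenergic and monoamine genes passed over all genes, and 0 by the gene-by-gene method. Leaving out each array gave 0 to 4 probe sets, and the 4 came without KCl replicate 1. The 743 genes at unadjusted p under 0.05 became 465 without probe sets under the median, 8676 and 5164 with these sets of weights, 1436 with the replicate block and 1133 (564 higher with norepinephrine, 569 with KCl) over all probe sets of the table. Leaving out arrays gave 317 to 3532: 317, 448 and 357 without norepinephrine replicates 1, 2 and 3 and 3532 without KCl replicate 2. The cause was not tested.

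The number of lists called, 16 on 6 arrays, was 0 with an estimated correlation, with or without KCl replicate 1, and 0 with fry. It was 9 without probe sets under the median, and 12 to 19 when each array was left out, and of the 16 lists 7 and 9 to 16 were still called there. The share of variance between treatments was 42.08% after subtracting the means of the replicate numbers. It was 18.18% to 46.03% when arrays were left out, the last without KCl replicate 2. With fewer arrays or with means subtracted, any grouping takes a larger share by chance. These shares are therefore not comparable with the share on 6 arrays, and a rise does not show a larger treatment effect. The replicate block called 0 genes and 16 lists. Residuals of arrays with equal numbers correlated at 0.301, 0.626 and 0.0852, so that not every pair passed 0.1 and the numbers were not taken to pair the samples. For number 3 another array correlated better, at 0.311.

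The genes and lists that turned direction had passed no test in the unweighted comparison of all arrays, except for the cholesterol synthesis list. That list had an opposite sign in camera without KCl replicate 1. Some lists that turned were called by camera in other settings. Without KCl replicate 2 these were DNA replication and S phase (adjusted p = 0.00358) and p53 targets (adjusted p = 0.00306). Without KCl replicate 3 they were EGF and FGF signalling (adjusted p = 0.00593) and potassium transport (adjusted p = 0.00925). Potassium transport was also called without norepinephrine replicate 1 (adjusted p = 0.0421). The second quantile normalization turned Dbh to 0.041 and Maob to 0.093, and centring turned Maob to 0.008. Array weights turned Th to 0.112. For lists the sign of the test turned while the median stood as follows. With fry it was -0.005 for mature neuron markers and -0.056 for the BMP and TGF-beta pathway. After quantile normalization it was -0.066 for DNA replication and S phase, -0.056 for pericyte, smooth muscle and fibroblast markers, -0.058 for ependymal and choroid plexus markers and -0.051 for the BMP and TGF-beta pathway. Without probe sets under the 30th percentile it was 0.028 for DNA replication and S phase, -0.111 for pericyte, smooth muscle and fibroblast markers and -0.066 for the BMP and TGF-beta pathway. Without those under the median it was 0.029 for DNA replication and S phase, -0.005 for mature neuron markers and 0.099 for pericyte, smooth muscle and fibroblast markers. With array weights it was -0.08 for potassium transport, -0.13 for the BMP and TGF-beta pathway and -0.056 for growth factors and receptors of EGF and FGF signalling.

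When each array was left out, Adra1b ranged from -0.342 to 0.116, Dbh from -0.315 to 0.14, Grk3 from -0.279 to 0.001, Maoa from -0.087 to 0.943, Maob from -0.256 to 0.186, Slc29a4 from -0.061 to 0.327, Slc6a4 from -0.319 to 0.002 and Th from -0.252 to 0.146. List medians ranged from -0.18 to 0.063 for activity-induced immediate early genes, -0.283 to 0.011 for adrenergic and monoamine genes, -0.171 to 0.024 for the BMP and TGF-beta pathway, 0.021 to 0.478 for cholesterol synthesis, -0.077 to 0.148 for DNA replication and S phase and -0.228 to -0.001 for ependymal and choroid plexus markers. They ranged from -0.266 to 0.059 for forebrain regional identity, -0.027 to 0.151 for growth factors and receptors of EGF and FGF signalling, -0.051 to 0.28 for p53 targets and apoptosis, -0.317 to 0.055 for pericyte, smooth muscle and fibroblast markers and -0.135 to -0.007 for voltage-gated calcium channels and calcium signalling. Signal over background was not available, so what it limits was not assessed.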

Other observations

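Gene families outside the fixed lists were looked at after the data were seen, 5 in all, and are given as values. Genes of the large mitochondrial ribosomal subunit (Mrpl) were higher with norepinephrine in 46 of 48 members, with a median of 0.33 on 6 arrays and 0.22 without KCl replicate 1. Those of the small mitochondrial subunit (Mrps) were higher in 27 of 29, with medians of 0.35 and 0.22. Catalytic core genes of the proteasome (Psmb) were higher in 10 of 11, with medians of 0.51 and 0.33. In the protocadherin beta cluster (Pcdhb), whose genes share sequence and whose probe sets are therefore not independent, 3 of 22 members were higher with norepinephrine, with medians of -0.21 and -0.25. Among chromodomain helicase genes (Chd), which include Chd7, 3 of 10 were higher with norepinephrine, with medians of -0.18 and -0.26. After a further quantile normalization the medians were 0.25, 0.23, 0.39, -0.08 and -0.28, so none turned. The families were picked for their values, so no test of them is given.

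Below, the test for an exchanged label, the tests of KCl replicate 1 as sole origin and the comparison of astrocyte markers with other lineages were chosen after the results were seen. The other tests were set before.

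KCl replicate 1 stood apart, with a slope of 0.748 on the mean of the other arrays where they had 0.989 to 1.09. A compressed scale alone is argued against, since after quantile normalization its mean correlation with the others was 0.9095, below the 0.9718 of the least similar pair among them. Of 1314 genes that parted the other arrays, 54.95% lay nearer to the KCl arrays on it, against 17.74% and 44.01% for KCl replicates 2 and 3 when treated likewise, so an exchanged label cannot be told apart from a correct one. For norepinephrine replicates 1, 2 and 3 the share nearer to their own group was 76.03%, 57.68% and 76.72%. On KCl replicate 2 most such genes lay nearer to the norepinephrine arrays. The genes for KCl replicates 2 and 3 were picked with KCl replicate 1, which stood apart, in the KCl group. On the first principal component KCl replicate 2 scored -40.12 and KCl replicate 1 85.66. The share for KCl replicate 2 can therefore not decide whether its label is right, which was not tested further. Cells of a non-neural type also stay open. Microglia markers lay highest of 4 such lists, at percentile 94.81 of matched random lists. Pericyte, ependymal and endothelial markers lay at percentiles 92.63, 32.11 and 31.4. None passed the limit set beforehand, and that limit does not exclude a small share of such cells. Of the 7 lists for lysosome, glycolysis, heat shock, cholesterol, stress response, circadian and microglia genes, 0 were called without this array (lowest adjusted p 0.252), but they were picked for that, so it decides nothing, and an effect of KCl in that culture was not tested.

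Astrocyte markers were higher with norepinephrine, with Gfap in front. KCl replicate 1 as the sole origin is argued against by the list means of the other 5 arrays, where a gap of 0.3469 between the groups exceeded the widest range within a group, 0.0469. A trend with brightness and gene length is argued against as well, since the median without KCl replicate 1, 0.29, lay at percentile 100 of matched random lists, whose central 95% ran from -0.0627 to 0.1132. In the same comparison neuroblast, mature neuron and myelinating markers lay at percentiles 99.96, 99.82 and 99.78, and oligodendrocyte precursor markers at 90.22. A high percentile there was therefore not particular to astrocyte genes. The random lists drew genes singly and held the arrays fixed, so these percentiles do not carry the spread between samples. Whether all differentiated lineages shifted alike cannot be told apart from a shift of astrocyte genes, because the astrocyte median exceeded that of 94 neuronal and oligodendrocyte genes by 0.1756 with a bootstrap interval of -0.029 to 0.356. That bootstrap drew genes and held the arrays fixed, so its interval does not carry the spread between samples. A treatment effect on astroglial genes or on the share of astroglial cells stays open as untested, since no cell counts or staining were analysed here and the list was not called with an estimated correlation (adjusted p = 0.0985, and 0.221 without KCl replicate 1).

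Oxidative phosphorylation genes were higher with norepinephrine in 33 of 33 members, of which 0 passed when adjusted over the list alone, and the list was not called with an estimated correlation (adjusted p = 0.29) or with fry (adjusted p = 0.517). Without KCl replicate 1 the list mean of the lowest norepinephrine array lay 0.0582 above that of the highest KCl array, less than the range of 0.3176 within a group. The adjusted p was 0.448 there with an estimated correlation. KCl replicate 1 as the main origin can therefore not be told apart from a difference between the treatments. The median of 0.27 without KCl replicate 1 lay at percentile 99.97 of random lists matched on brightness and gene length. The central 95% of those lists ran from 0.0033 to 0.1858. On these arrays the list therefore stood above genes of like brightness and length drawn singly. For genes that move together that interval is too narrow, so whether such a trend is the whole of it cannot be decided. Differences in RNA quality between samples stay open as untested, as does a treatment effect on mitochondria. The genes of this list move together between samples, with an estimated correlation of 0.436.

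The other 14 lists called on 6 arrays differed in how they stood among random lists matched on brightness and gene length. On 6 arrays and without KCl replicate 1, the percentiles were 98.84 and 99.77 for mitosis and G2/M, 93.79 and 99.99 for quiescence, 83.51 and 97.65 for neural stem, 99.99 and 99.93 for interferon, 99.99 and 99.97 for reactive astrocyte and 97.96 and 99.92 for histone genes. They were 58.82 and 16.57 for ribosomal proteins, 65.65 and 32.17 for heat shock, 75.17 and 39.09 for stress response and 86.86 and 87.45 for circadian genes. For lysosome, hypoxia and cholesterol genes they were 95.53 and 52.98, 99.83 and 37.02, and 96.74 and 42.48. For microglia markers they were 0.41 and 19.15.

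The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes at adjusted p under 0.05 the real count of 0 is met by 10 of the 10 by construction, with a highest other value of 0. At an unadjusted p under 0.05, 4 splits gave at least the real 743, and the highest other gave 2980. For lists, 5 splits gave at least the real 16, with 19 as the highest other, and for the share of variance 4 gave at least the real 20.08%, with 35.1% as the highest other. Camera with a preset correlation called the astrocyte list in the real split (adjusted p = 7.7e-13). It also called that list in others, at adjusted p = 5.9e-06, 1.3e-05, 0.00073, 0.0011, 0.0094 and 0.0115. In the remaining splits the adjusted p was 0.663, 0.723 and 0.788. The splits with 2980 and 2781 genes, several times the real count, both set norepinephrine replicate 2 and KCl replicate 2 on one side and KCl replicates 1 and 3 on the other, which points to a structure of the samples other than treatment.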
